A study of Rattus norvegicus with 12 samples.

How the data were processed

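Small RNA of rat islet cells, isolated with TRIzol, was sequenced on an Illumina NextSeq 500. Per the file headers, the deposited values are read counts, given by the authors per mature miRNA and precursor without normalization. The labels name FastQC 0.11.7, cutadapt 1.14, Bowtie and edgeR 3.18.1. The Bowtie version, the miRNA reference and the genome build are not given in the sources used here.

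The table held 436 entries for 389 mature miRNAs, 388 distinct sequences and 291 precursors, and 9 emptied lines that were not used. A miRNA with several precursors appears once per precursor (42 miRNAs, 20 with differing counts), and the entry with the most reads was kept, so that each miRNA entered once. The filter filterByExpr on the 4 groups removed 10 and left 378 sequences. Library totals ran from 4103734 to 8519446 reads and TMM factors from 0.147 to 2.16, and the biological coefficient of variation was 0.523. Levels are TMM-normalised CPM.

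Differences were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 on all 12 libraries, with 1 mean per group, at a Benjamini-Hochberg adjusted p of 0.05. The comparisons were tail against head at each age and over both, 24W against 6W in each region and over both, and the interaction. Lists of miRNAs were tested with camera (limma 3.58.1) at a preset correlation of 0.01 where at least 3 members were tested. The Dlk1-Dio3, neuronal and other lists, the comparisons, the tests, the rule for named miRNAs and most of the other settings were chosen before the data were examined. Alternatives described as chosen after seeing the data, and the tests of explanations, were not. The correlations across libraries and the exact permutation tests of single measures were not among the planned tests either. The rule for named miRNAs took, where fewer than 3 passed in a comparison, the 5 with the smallest p at an average log2 CPM of at least 3, with the 4 most abundant members of each list, the 5 most abundant miRNAs and miR-375. miRNAs called in another setting and those in the brain-type group were named after their values were seen.

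Alternatives were DESeq2 1.42.0, limma-voom, RLE and total-count scaling, looser and stricter filters (CPM of at least 10 in at least 3 libraries), robust fitting, a replicate block, fits without each library, an estimated correlation and fry. Single measures were compared in R with two-sided exact permutation tests within age or region (400 relabelings). Correlations across libraries were computed in Python 3.11.15 with scipy 1.17.1, and their p-values came from 100000 permutations with numpy 2.4.6. For 3 libraries against 3 an exact test cannot go below p = 0.1.

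The edgeR test was tested on simulated data with the counts' own spread. At 24W it called 10.4% of miRNAs changed 2-fold, 64.2% changed 4-fold and 90.9% changed 8-fold, and over both ages 40.3%, 98.5% and 100%. Of 178 unchanged miRNAs it called 4 at 24W and 5 over both ages. There 200 of the 378 miRNAs changed at once, and miRNAs shared no library effect. So many changes loosen the adjusted threshold, so these rates may not hold for the deposited data. In simulations of the Dlk1-Dio3 list with no group difference but a shared library effect of 1 log2 unit (SD), camera called it in 66 of 100 at the preset correlation and in 16 of 100 with an estimated one. Without the shared effect these numbers were 4 and 2. The simulated shared effect was larger than the SD of the list mean within groups, which ran from 0.304 in 24W head to 0.724 in 24W tail. Calls in the simulations were at an unadjusted camera p under 0.05, so the rates may overstate those of the tests reported here.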

Results

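Small RNA libraries were sequenced from islet cells of the pancreatic head and tail of male Sprague-Dawley rats, to compare miRNA levels between both parts of the organ. Islets are the endocrine cell clusters of the pancreas and lie within enzyme-secreting acinar tissue. The sample titles give 4 groups of 3 libraries each, namely 6W head, 6W tail, 24W head and 24W tail, where W was read as weeks. The series description speaks of rats of 24 weeks alone, so the 6-week groups rest on the titles. Nothing states that the replicates are separate animals, so the p-values measure the spread between these samples, which may be technical.

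The 12 libraries held 4103734 to 8519446 miRNA reads each, over 388 distinct mature sequences. miR-148a-3p alone took 25.4% of the reads in 24W tail replicate 1 (exact Clopper-Pearson 95% interval 25.39 to 25.46) and 94.3% in 24W head replicate 2 (94.31 to 94.34). These intervals cover counting error only, because PCR reads are not independent molecules. The share averaged 64.2% ± 24.8 (SD, n = 3) in 6W head, 50.003% ± 22.4 (SD, n = 3) in 6W tail, 72.3% ± 20.8 (SD, n = 3) in 24W head and 46.0% ± 21.3 (SD, n = 3) in 24W tail. The tail libraries averaged 48.0% and the head libraries 68.2%, a difference of -20.2 percentage points that did not exceed the spread (two-sided exact permutation within age, p = 0.155, adjusted p = 0.479 over 34 comparisons, n = 6 each). All other miRNAs together had 483289 reads in 24W head replicate 2 and up to 4286741 in 24W tail replicate 1, so low levels are least precise in the former. The next most abundant miRNAs included miR-7a-5p, miR-143-3p, miR-26a-5p and miR-375-3p.

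**Figure D1:**
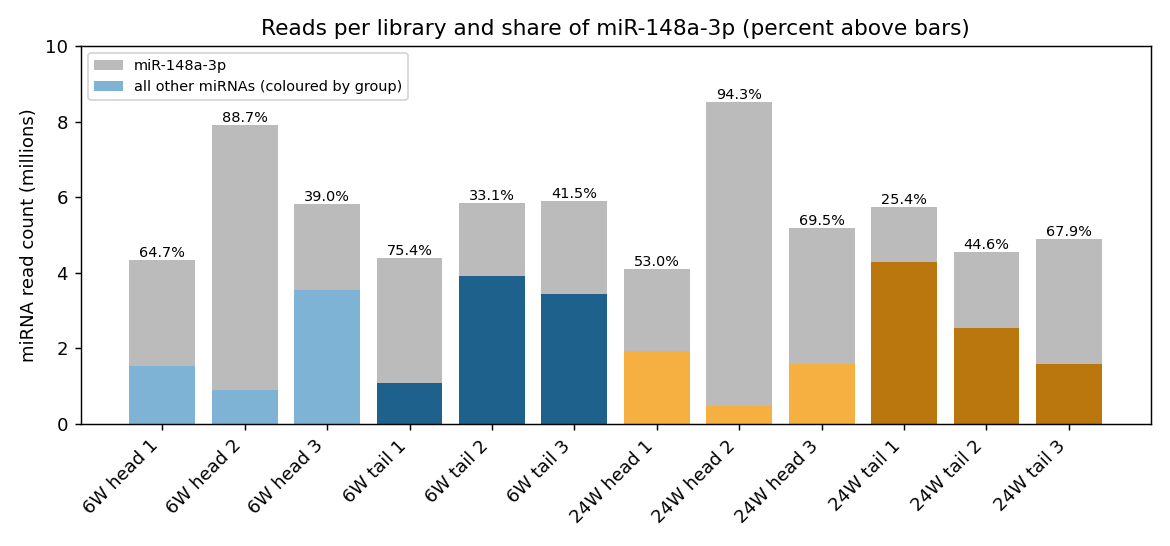
miRNA reads per library (bars), with miR-148a-3p in grey and all other miRNAs coloured by group, and the share of miR-148a-3p in percent above each bar. The share runs from 25.4% to 94.3%, and both libraries with the highest share are head libraries.

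The comparison of tail with head over both ages asked whether islets differ between these regions. miR-375-3p, which restrains insulin secretion and is needed for a normal beta cell mass, stood at 9989.7 ± 1749 normalised CPM in head and 17195 ± 7386 in tail (SD, n = 6 each), a log2 fold change of 0.75 ± 0.29 (SE, edgeR adjusted p = 0.309). miR-7b had a log2 fold change of 1.10 ± 0.38 (SE, edgeR adjusted p = 0.309) and miR-7a-2-3p one of 1.44 ± 0.38 (SE, edgeR adjusted p = 0.138). miR-7a-5p and miR-7b differ by 1 base, so the values of both are uncertain. miR-152-3p stood at 2153 ± 1544 normalised CPM in head and 625 ± 208 in tail (SD, n = 6 each), a log2 fold change of -1.67 ± 0.39 (SE, edgeR adjusted p = 0.101), and it differs from the far more abundant miR-148a-3p at 3 of 21 bases. miR-148a-3p had -2.06 ± 0.81 (SE), and -1.17 without 6W head replicate 2 or -1.10 without 24W head replicate 2. None of these passed in edgeR's main test, which called 0 of 378 miRNAs, with 51 at an unadjusted p under 0.05 where chance gives 18.9. A replicate block by library number gave 13 calls in edgeR (adjusted p = 0.0288 to 0.0342), though no source states a pairing. Higher in tail were miR-7b, miR-7a-2-3p, miR-298-5p, miR-298-3p, miR-325-5p, miR-325-3p, miR-1224 and miR-129-5p. Lower in tail were miR-152-3p, miR-1298, miR-9a-3p, miR-21-5p and miR-338-5p. DESeq2 called 8, namely miR-7a-2-3p and miR-298-3p, higher in tail, and miR-152-3p, miR-9a-3p, miR-9a-5p, miR-124-3p, miR-1298 and miR-219a-2-3p, lower in tail, and limma-voom called 0. Without 24W head replicate 1, edgeR called 5, namely miR-1298, miR-9a-3p, miR-219a-2-3p, miR-152-3p and miR-124-3p, all lower in tail. These 5 and miR-9a-5p stood above the other 9 libraries in 6W head replicate 2 and in 24W head replicates 2 and 3. Those libraries were picked by their miR-1298 reads. Leaving out 24W head replicate 1 keeps only 24W head libraries of that kind, so these calls rest on those libraries.

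Of the 15 miRNA lists tested over both ages, camera placed 2 higher and 5 lower in tail than the other miRNAs. The Dlk1-Dio3 imprinted cluster, a large group of maternally expressed miRNAs, had 60 of 60 members above 0 and a median log2 fold change of 0.70, with miR-127-3p at 0.80 ± 0.39 (SE; 0.53 without 6W tail replicate 3) and miR-341 at 0.71 ± 0.35 (SE; 0.41 without 24W tail replicate 1). The islet endocrine list had 9 of 10 members above 0 and a median of 0.73. Members below 0 numbered 12 of 12 in miR-17-92 and paralogs (median -0.56), 9 of 9 in the mesenchymal and smooth muscle list (median -0.68), 4 of 4 in the gut and liver list (median -1.01), 7 of 7 in the leukocyte list (median -0.55) and 9 of 13 in the neuronal list (median -0.84). The preset adjusted p of camera was 1.07e-13 for Dlk1-Dio3, 0.000564 for the islet list and between 0.0212 and 0.0459 for the other 5. None was called with the members' correlation estimated from the data: adjusted p = 0.433 with an estimated correlation for each of the 7. Adjusted over the list alone, 5 neuronal miRNAs (4 with negative values and miR-129-5p at 1.09 ± 0.38 SE), miR-7a-2-3p of the islet list and miR-29c-5p of the miR-29 list passed, and 0 members of the other lists passed. With total counts in place of TMM factors, the median of all miRNAs moved from -0.031 to 0.79, and the mean log2 fold changes of the neuronal, gut and liver, leukocyte and miR-17-92 lists turned positive, while camera still placed them below the other miRNAs. The Dlk1-Dio3, islet and miR-17-92 lists were called in each of the 12 fits without 1 library, the leukocyte list in 4 of them, the neuronal list in 6, the mesenchymal list in 8 and the gut and liver list in 10. The leukocyte mean of -0.59 became -1.09 without 6W tail replicate 2, -1.07 without 24W tail replicate 3 and -0.34 without 24W head replicate 3, which also took miR-17-92 from -0.52 to -0.35. The mesenchymal mean went from -0.69 to -0.36 without 6W head replicate 3, the neuronal one from -1.13 to -0.61 without 6W head replicate 2 and the gut and liver one from -0.998 to -0.51 without 24W head replicate 2. With the acinar level as covariate, chosen after seeing the data, the gut and liver list (mean -0.52, adjusted p = 0.0823) and miR-17-92 (-0.36, adjusted p = 0.0632) were not called, and the means of the Dlk1-Dio3 and islet lists went from 0.72 and 0.70 to 0.34 and 0.45.

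The acinar list (miR-216a, miR-216b and miR-217) had 6 of 6 members below 0 in tail against head over both ages (median -0.36) and at 6W (median -1.003; mean -0.95, but -2.48 without 6W tail replicate 1 and -0.44 without 6W tail replicate 3), and 4 of 6 above 0 at 24W (median 0.11, camera adjusted p = 0.904). Over both ages its mean was 8.26 log2 CPM in head and 7.44 in tail (exact permutation within age, p = 0.305, adjusted p = 0.61, n = 6 each), and camera did not call it (adjusted p = 0.082). miR-217-5p stood at 6454 ± 2661 normalised CPM in head and 4355 ± 3389 in tail (SD, n = 6 each). Across the 12 libraries the acinar and islet lists had a Pearson's r of -0.80 (permutation p = 0.00168, adjusted 0.00504 over 6 relations) and a Spearman's rho of -0.64 (permutation p = 0.0293, adjusted 0.0561, which did not pass). The 6 relations were not among the planned tests. Their permutations moved libraries freely across the groups, as if all 12 were independent, which is not known. With group means removed, the r of the acinar and islet lists was -0.80. The r was -0.56 within head, -0.94 within tail, and -0.56 without 6W tail replicate 3 and 24W tail replicate 1, the libraries farthest from the median acinar level. The acinar list also had an r of -0.65 with the Dlk1-Dio3 cluster (permutation p = 0.024, adjusted 0.0387; rho -0.78, p = 0.00394, adjusted 0.0236), and -0.50 without those libraries. The islet list and the Dlk1-Dio3 cluster had an r of 0.80 (permutation p = 0.00153, adjusted 0.00504; rho 0.62, p = 0.0374, adjusted 0.0561), and 0.67 without those libraries.

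**Figure D2:**
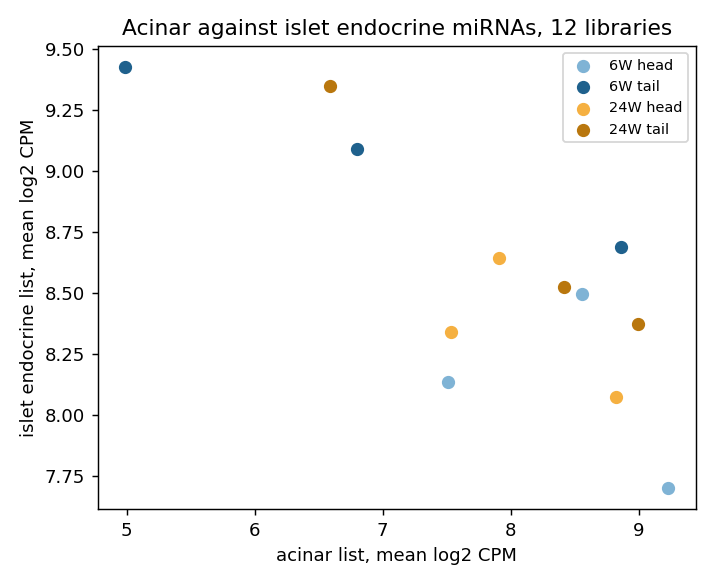
Mean log2 CPM of the islet endocrine list (vertical axis) against that of the acinar list (horizontal axis), with 1 point per library coloured by group. Islet levels were lower where acinar levels were higher (Pearson's r = -0.80, n = 12), and 6W tail replicate 3 lies farthest to the left.

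miR-1298, miR-219a-2-3p and miR-124-3p had most of their reads in 6W head replicate 2 and in 24W head replicates 2 and 3. In these 3 libraries miR-1298 had 61 to 139 reads, miR-219a-2-3p 90 to 120 and miR-124-3p, a neuron-enriched miRNA, 52 to 87. The other 9 libraries held at most 4, 7 and 14 reads of them, and at such counts a fitted fold change depends on the prior count. Leaving the 3 libraries out, chosen after seeing the data by these counts, leaves 2 libraries in 6W head and 1 in 24W head. The loss of the neuronal list there (camera adjusted p = 0.781) follows from that choice and tests nothing, and edgeR called 0 with and without them.

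**Figure D3:**
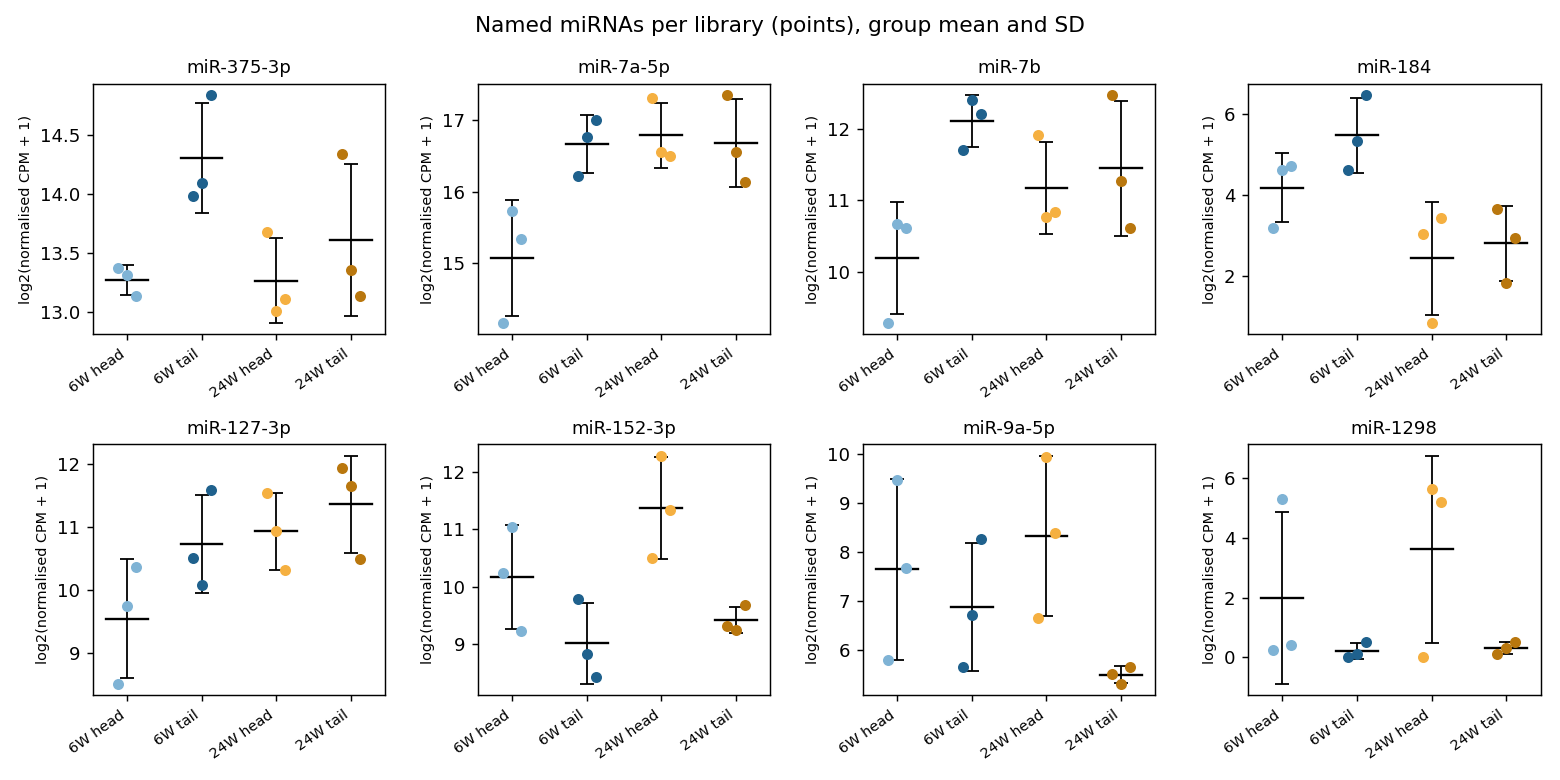
log2(normalised CPM + 1) of 8 miRNAs in each library (points), with the group mean (line) and SD (bar), n = 3 per group. miR-1298 is high in 1 of 3 libraries of 6W head and in 2 of 3 of 24W head, and miR-375-3p overlaps between head and tail at 24W.

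At 24W alone, tail against head, miR-9a-5p, a neural miRNA, had a log2 fold change of -3.41 ± 0.97 (SE) and miR-152-3p one of -2.12 ± 0.56 (SE). miR-122-5p, the main liver miRNA, stood at 56.4 ± 56.3 normalised CPM in 24W head and 6.37 ± 3.94 in 24W tail (SD, n = 3 each), a log2 fold change of -3.14 ± 0.90 (SE). 24W head replicate 2 alone had 121 CPM of it, and without this library miR-122-5p had -1.85 and miR-9a-5p -2.21. All 3 missed the threshold (edgeR adjusted p = 0.365): edgeR called 0 miRNAs, with 20 at an unadjusted p under 0.05, DESeq2 called 5 (miR-9a-5p, miR-9a-3p, miR-122-5p, miR-152-3p and miR-124-3p, all lower in tail) and limma-voom 0. These 5 except miR-122-5p stood above the other 9 libraries in 24W head replicates 2 and 3 and in 6W head replicate 2. Of 378 miRNAs, which are not independent, libraries did not overlap between head and tail for 34 at 24W and 40 at 6W, and between ages for 53 in head and 28 in tail, where chance gives 10% for 3 against 3. In one direction, 6 did not overlap between head and tail at both ages, and 7 between ages in both regions, where chance gives 0.5%. Camera placed the Dlk1-Dio3 cluster (58 of 60 members above 0) and the islet list (9 of 10) higher, and the neuronal (9 of 13 below 0), gut and liver (4 of 4), mesenchymal (9 of 9), leukocyte (7 of 7) and miR-17-92 (11 of 12) lists lower in tail. None held: adjusted p = 0.398 with an estimated correlation for the neuronal and the gut and liver lists, and 0.505 to 0.516 for the other 5. Adjusted over the list alone, 6 neuronal miRNAs and miR-122-5p of the gut and liver list passed, and 0 members of the other lists passed. With total counts the median of all miRNAs moved from 0.10 to 1.51 and the means of all 5 lower lists turned positive, and camera then called 5 lists. The number of lists called was 2 without 24W tail replicate 1, where Dlk1-Dio3 was lost, and 4 without 24W head replicate 3 or without 24W tail replicate 2. Of the 6 fits without 1 library, the neuronal list was called in 6, the Dlk1-Dio3 and the gut and liver lists in 5, the islet and leukocyte lists in 3 and the mesenchymal and miR-17-92 lists in 2. The gut and liver mean went from -1.52 to -0.55 and the neuronal mean from -1.69 to -1.10 without 24W head replicate 2, and the leukocyte, miR-17-92 and mesenchymal means from -0.61, -0.45 and -0.66 to -0.045, -0.070 and -0.16 without 24W head replicate 3. The islet and Dlk1-Dio3 means of 0.42 and 0.59 became 0.029 and 0.16 without 24W tail replicate 1 (leukocyte -0.34, miR-17-92 -0.18), 0.68 and 0.97 without 24W tail replicate 3 (leukocyte -1.51, miR-17-92 -0.85) and 0.70 and 0.98 without 24W head replicate 1 (mesenchymal -0.37). The leukocyte mean was -0.27 without 24W tail replicate 2, and this list was not called with the acinar level as covariate (adjusted p = 0.0758).

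At 6W, miR-7b had the smallest tail-against-head p-value of the miRNAs at an average log2 CPM of at least 3. It stood at 1273 ± 563 normalised CPM in 6W head and 4479.5 ± 1064 in 6W tail (SD, n = 3 each), a log2 fold change of 1.82 ± 0.54 (SE). miR-7a-5p had 1.49 ± 0.51 (SE), miR-129-5p 1.67 ± 0.54 (SE; 0.94 without 6W tail replicate 3), miR-1224 2.22 ± 0.75 (SE; 1.02 without that library) and miR-29c-5p 1.20 ± 0.41 (SE). None passed in edgeR's main test (adjusted p = 0.542 for all 5), which called 0 miRNAs, with 32 at an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. A replicate block by library number gave 1 call in edgeR, miR-7b (log2 fold change 1.91, adjusted p = 0.0307). Camera placed the Dlk1-Dio3 cluster (57 of 60 members above 0) and the islet list (9 of 10) higher, and the acinar (6 of 6 below 0) and miR-17-92 (11 of 12) lists lower in tail. None held: adjusted p = 0.543 with an estimated correlation for the islet list and 0.554 for the other 3. In every list 0 members passed when adjusted over the list alone. The Dlk1-Dio3 and islet lists were called in each of the 6 fits without 1 library, the acinar list in 3 and the miR-17-92 list in 4. The acinar, Dlk1-Dio3 and miR-17-92 means of -0.95, 0.86 and -0.60 became -0.46, 0.55 and -0.32 without 6W head replicate 1 and -0.44, 0.50 and -0.33 without 6W tail replicate 3. Without 6W tail replicate 1 the acinar and miR-17-92 means became -2.48 and -0.91, and without 6W tail replicate 2 the acinar list was not called (mean -0.68). With the acinar level as covariate, miR-17-92 was not called (mean -0.14, adjusted p = 0.514) and the Dlk1-Dio3 and islet means went from 0.86 and 0.97 to 0.20 and 0.55.

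The tail-against-head values at both ages had a Pearson's r of 0.64 and a Spearman's rho of 0.62 across the 378 miRNAs, which are not independent replicates, and 75.4% had the same sign. The r was 0.37 without 6W head replicate 2, 0.41 without 24W tail replicate 1, and 0.034 without the 3 head libraries, which leaves 1 library in 24W head. The change of the tail-against-head contrast between ages was tested as an interaction. miR-122-5p had an interaction of -4.30 ± 1.24 (SE; -3.03 without 24W head replicate 2) and miR-7a-5p one of -1.55 ± 0.71 (SE, edgeR adjusted p = 0.996 for both). miR-7a-5p stood at 37954 ± 18131 normalised CPM in 6W head, 106356 ± 28205 in 6W tail, 117001 ± 38938 in 24W head and 111910 ± 49621 in 24W tail (SD, n = 3 each). edgeR called 0 miRNAs, with 4 at an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. Adjusted over the list alone, miR-122-5p passed in the gut and liver list.

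**Figure D4:**
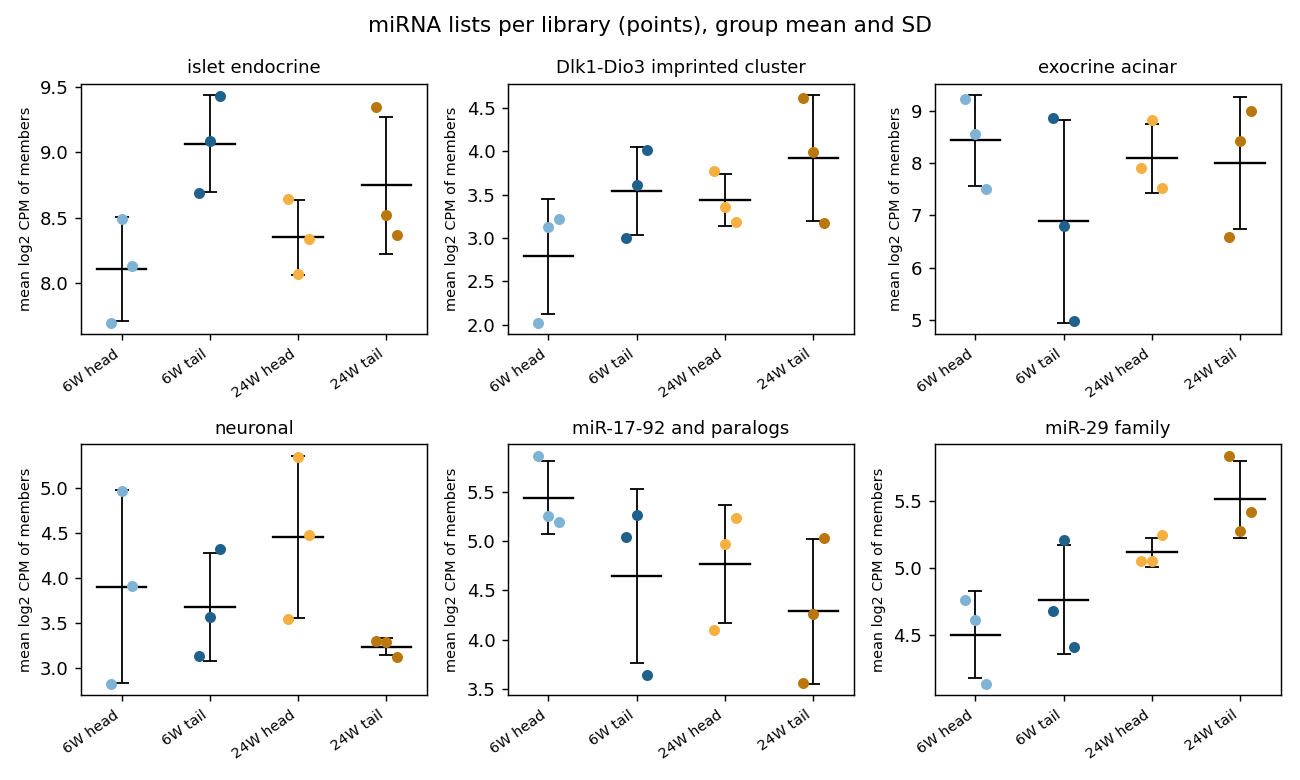
Mean log2 CPM of the members of 6 lists in each library (points), with the group mean (line) and SD (bar), n = 3 per group. The acinar list has its widest spread in 6W tail (SD 1.94), and the neuronal list its narrowest in 24W tail (SD 0.0957).

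Between 24W and 6W, over both regions, miR-184, an islet miRNA that limits beta cell expansion, stood at 34.7 ± 27.9 normalised CPM at 6W and 6.46 ± 4.13 at 24W (SD, n = 6 each), a log2 fold change of -2.22 ± 0.54 (SE). miR-488-3p had 1.39 ± 0.36 (SE) and, in the Dlk1-Dio3 cluster, miR-136-5p had 1.00 ± 0.29 (SE) and miR-154-5p 1.34 ± 0.41 (SE). All 4 missed the threshold (edgeR adjusted p = 0.265): edgeR called 0 miRNAs, with 44 at an unadjusted p under 0.05, DESeq2 called 3 (miR-184 and miR-130b-3p lower, miR-488-3p higher) and limma-voom 0. miR-375-3p had -0.31 ± 0.29 (SE, edgeR adjusted p = 0.746), and -0.14 without 6W tail replicate 3 or -0.54 without 24W tail replicate 1. Camera placed the Dlk1-Dio3 cluster (54 of 60 members above 0, median 0.50) and the miR-29 family (6 of 6, median 0.57) higher at 24W, and miR-17-92 and paralogs (11 of 12 below 0, median -0.61) and the X-linked miR-322 cluster (9 of 9, median -0.52) lower. Examples are miR-29b-3p at 0.91 ± 0.30 (SE) and miR-92a-3p, of a proliferation-linked family, at -1.22 ± 0.42 (SE), neither of which passed. None of the lists held: adjusted p = 0.447 with an estimated correlation for miR-29, 0.850 for Dlk1-Dio3 and miR-17-92 and 0.892 for miR-322. Adjusted over the list alone, miR-184 passed in the islet list, which camera did not call (adjusted p = 0.929), and 0 members of the other lists passed. The Dlk1-Dio3, miR-29 and miR-17-92 lists were called in each of the 12 fits without 1 library and miR-322 in 7. The Dlk1-Dio3 mean of 0.50 became 0.30 without 24W head replicate 1 and 0.28 without 24W tail replicate 1, and the miR-322 mean went from -0.52 to -0.11 without 6W head replicate 3. miR-322 was not called with the acinar level as covariate (adjusted p = 0.193) or with total counts (adjusted p = 0.0505), which took the Dlk1-Dio3, miR-29, miR-17-92 and miR-322 means to 0.10, 0.25, -1.23 and -1.01. The acinar list had a median of 0.11 (camera adjusted p = 0.854).

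Within head alone, miR-7a-5p had a log2 fold change between ages of 1.62 ± 0.51 (SE) and miR-122-5p one of 2.78 ± 0.89 (SE; 1.49 without 24W head replicate 2), and neither passed (edgeR adjusted p = 0.776). edgeR called 0 miRNAs, with 21 at an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. Camera placed the Dlk1-Dio3 cluster and the miR-29 family higher and the miR-17-92 list lower at 24W, with adjusted p = 0.755 with an estimated correlation for each. With total counts the median of all miRNAs moved from 0.035 to -0.92 and the means of the Dlk1-Dio3 and miR-29 lists turned negative, and miR-29 was not called (adjusted p = 0.105). In the gut and liver list, miR-122-5p passed when adjusted over the list alone. Without 24W head replicate 2, 5 lists were called, and without 24W head replicate 1 or replicate 3, 2 were. Of the 6 fits without 1 library, Dlk1-Dio3 was called in 6, miR-17-92 in 5 (lost without 24W head replicate 1) and miR-29 in 2 (lost without 6W head replicate 2 or 3 and 24W head replicate 1 or 3). The Dlk1-Dio3 mean of 0.63 became 0.33 without 6W head replicate 1 and 0.22 without 24W head replicate 1, and the miR-17-92 mean of -0.75 became -0.48 without 6W head replicate 1 and -1.18 without 24W head replicate 3, and -0.47 with the acinar level as covariate.

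Within tail alone, miR-184 stood at 50.4 ± 33.5 normalised CPM at 6W and 6.95 ± 4.497 at 24W (SD, n = 3 each), a log2 fold change of -2.85 ± 0.78 (SE, edgeR adjusted p = 0.825). edgeR called 0 miRNAs, with 13 at an unadjusted p under 0.05, DESeq2 called 1 (miR-184) and limma-voom 0. Camera placed the Dlk1-Dio3, miR-29 and acinar lists higher and the neuronal, gut and liver, miR-17-92 and miR-322 lists lower at 24W. None held: adjusted p = 0.491 with an estimated correlation for miR-29 and 0.624 for the other 6. In the islet list, miR-184 passed when adjusted over the list alone. The number of lists called was 3 without 24W tail replicate 1, where the mean of the Dlk1-Dio3 cluster went from 0.36 to -0.065, and 4 without 6W tail replicate 2. Of the 6 fits without 1 library, miR-29 and miR-322 were called in 5, Dlk1-Dio3 in 4, the neuronal, gut and liver and miR-17-92 lists in 3 and the acinar list in 2. The acinar mean of 0.62 became 2.12 without 6W tail replicate 1, 0.36 without 6W tail replicate 2, 0.14 without 6W tail replicate 3, 1.05 without 24W tail replicate 1 and 0.015 without 24W tail replicate 3. Without 6W tail replicate 1 the gut and liver, miR-17-92 and Dlk1-Dio3 means went from -0.83, -0.60 and 0.36 to -0.20, -0.33 and 0.20, and without 6W tail replicate 3 the neuronal mean from -0.65 to -0.19 and Dlk1-Dio3 to 0.74. The miR-17-92 mean was -0.36 without 6W tail replicate 2 (miR-322 from -0.74 to -0.48), -0.33 without 24W tail replicate 1 and -1.09 without 24W tail replicate 3 (Dlk1-Dio3 0.69). With the acinar level as covariate, 4 of the 7 lists were called: the neuronal list (mean -0.33, adjusted p = 0.566) and miR-322 (-0.39, adjusted p = 0.225) were lost, the acinar list by construction, and the means of Dlk1-Dio3, gut and liver and miR-17-92 became 0.84, -1.35 and -0.92. Across miRNAs the age values in head and tail had a Pearson's r of 0.49 and a Spearman's rho of 0.45, with 66.1% of one sign. The r was 0.23 without 6W tail replicate 1, 0.27 without 24W tail replicate 1, and 0.30 without 24W head replicate 3 or without the 3 head libraries.

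The let-7, p53 and senescence-linked and striated muscle lists were not called in any of the 7 comparisons of the main test (camera, smallest adjusted p 0.0510 for striated muscle at 24W). For tail against head, the striated muscle list was called in 5 of 14 alternatives at 24W and 5 of 20 over both ages. The p53 list was called there in 1 of 14 and 2 of 20, and in 1 of 14 at 6W. In the main test the miR-200 and miR-30 lists were called in the interaction alone, and not with the correlation estimated (adjusted p = 0.84 with an estimated correlation for miR-200 and 0.64 for miR-30). The erythroid, endothelial and hypoxia lists had 2, 2 and 1 tested members and the Igf2/H19 list 0, too few for a list test. Over both ages, tail against head gave -0.42 ± 0.39 (SE) for miR-451-5p of red blood cells, -0.0099 ± 0.45 (SE) for miR-126a-3p of endothelium and 0.32 ± 0.28 (SE) for the hypoxia-induced miR-210-3p, and 24W against 6W gave -0.51 ± 0.39, -0.60 ± 0.46 and 0.25 ± 0.28 (SE), none of which passed with edgeR. Without 24W head replicate 2, miR-451-5p had 0.070 and -0.97, and without 6W tail replicate 3 miR-126a-3p had -0.49 and -0.10. The averages of miR-451-5p hide an interaction of -1.89 (-2.31 to -0.89 in fits without 1 library), which did not pass. The erythroid list averaged 2.54 ± 1.06 log2 CPM in 24W tail (SD, n = 3) and 4.23 to 4.43 in the other groups. Its highest 24W tail library (3.71) lay just below the lowest other library (3.79). This difference was not tested. In tail against head, miR-210-3p had 0.15 without 6W tail replicate 2 and 0.48 without 6W tail replicate 3. Between ages it had 0.42 and 0.10 without these libraries.

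The hairpins lie at the following positions in the deposited table, whose genome build is not given in the sources used here. miR-375 is on chromosome 9 (82161716 to 82161790), miR-148a on chromosome 4 (81013269 to 81013365), miR-184 on chromosome 8 (97175657 to 97175733), miR-152 on chromosome 10 (84719319 to 84719403) and miR-122 on chromosome 18 (60755285 to 60755369). The hairpins of the 60 tested Dlk1-Dio3 members span 133682965 to 133894072 on chromosome 6. Whether the hairpins lie in exons or introns of other genes was not analysed here.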

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

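All tests of explanations in this part, and the wording of what each would show, were set after the values had been seen, and the interaction itself was planned before the data were examined. The tail-against-head contrast differed between 24W and 6W for 6 lists by the interaction test (camera at the preset correlation). The neuronal list (adjusted p = 0.000468), the islet list (0.00906) and the Dlk1-Dio3 cluster (0.00300) had lower values at 24W, with mean interactions of -1.13, -0.55 and -0.27 log2 units (-1.89 to -0.51, -0.94 to -0.25 and -0.70 to 0.16 in fits without 1 library, with Dlk1-Dio3 above 0 without 6W head replicate 1, 6W tail replicate 3, 24W head replicate 1 or 24W tail replicate 3). The acinar (0.00300), miR-200 (0.0258) and miR-30 (0.0469) lists had higher ones, with means of 1.05, 0.45 and 0.40 (0.56 to 2.67, 0.17 to 1.16 and 0.26 to 0.74 in fits without 1 library). With an estimated correlation none was called: adjusted p = 0.64 for the neuronal, islet, acinar and miR-30 lists and 0.84 for the Dlk1-Dio3 and miR-200 lists. The neuronal list was called in each of the 12 fits without 1 library, the acinar and Dlk1-Dio3 lists in 7, the islet list in 6, the miR-200 list in 4 and the miR-30 list in 2. The number called was 1 without 6W tail replicate 2, 2 without 6W tail replicate 3 or 24W tail replicate 3, and 3 without 6W head replicate 1, 24W head replicate 1, 24W head replicate 3 or 24W tail replicate 2. With total counts the means of the islet and Dlk1-Dio3 lists turned positive (0.33 and 0.78) and miR-30 was not called (adjusted p = 0.0741). With the acinar level as covariate, 2 lists were called, the neuronal list and the gut and liver list, which was not among the 6: miR-200 became -0.12 (adjusted p = 0.58), Dlk1-Dio3 0.27 (0.106), islet -0.22 (0.186) and miR-30 0.20 (0.403), and the acinar list was lost by construction. Chance could not be excluded for the 6 lists, since 31 of 100 splits of the libraries gave at least as many and the highest other gave 9.

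miR-148a-3p exceeded its median over the other 10 libraries by 3.50 log2 units in the 2 libraries with the highest share, 6W head replicate 2 and 24W head replicate 2. RNA from acinar cells would bring the acinar miRNAs along, and the highest excess of an acinar member was 1.137 (SD of the list over the other libraries 1.31). The 2 libraries were picked by miR-148a-3p itself, which raises its own excess above those of other miRNAs, so this comparison cannot decide. Over all 12 libraries the acinar list had an r of 0.58 with miR-148a-3p (permutation, adjusted p = 0.0572). More of the miR-148a precursor would raise both arms, and miR-148a-5p exceeded its median by 1.04 (SD 1.32), which cannot decide for the same reason. Over all 12 libraries, with none picked, the ratio of the 3p to the 5p arm of miR-148a ranged 24.5-fold and ranked 2 of 53 in spread. This argues against more precursor as the whole source. Acinar RNA, arm stability, library preparation and a difference between the regions stay open.

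miR-148b-3p had 0.237 to 0.403% of the reads of miR-148a-3p in every library, a highest ratio 1.70 times the lowest, and ranked 1 of 256 miRNAs for a constant ratio. It differs from miR-148a-3p at 2 of 21 bases, and reads of miR-148a-3p assigned to it may account for this. Shared regulation of the family stays open too: miR-148b-5p did not follow miR-148a-3p (percentile 53.9 of ratio spread), but nor did miR-148a-5p (percentile 16.4), so the 5p arm cannot decide. miR-152-3p, at 3 differing bases, had a ratio that ranged 6.50-fold (0.0774 to 0.503%), which argues against assigned reads as its whole source. The bound on the range replaced a first criterion, a ratio spread among the lowest 5% of miRNAs, after that one had been met by both miR-148b-3p (percentile 0.391) and miR-152-3p (percentile 0.781), so a part of the miR-152-3p reads stays open.

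miR-1298, miR-219a-2-3p and miR-124-3p were high in the 3 head libraries picked by at least 50 reads of miR-1298. Scaling is argued against, since the unscaled counts of miR-219a-2-3p and miR-124-3p together were 7.89 times as high in the lowest of the 3 libraries as in the highest of the other 9. RNA of a neural tissue or cell, a candidate source, was not decided, since 4 of the 12 other members of the neuronal list were above all 9 libraries in all 3. With miR-219a-2-3p they were 5 of 13, a larger share than the 10 of all 378 tested miRNAs. Those 10 include miR-1298, which picked the libraries. A difference between head and tail islets was not decided either (exact permutation p = 0.14 for the neuronal list, n = 6 each), and both stay open.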

How the results depend on the processing

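The added alternatives (miR-148a-3p left out, the acinar level as covariate, the 3 head libraries left out, the precursor entry with the fewest reads, and total counts and leave-one-out fits for lists) were chosen after seeing the data. Other pseudocounts, meant for a table of normalized values, were not run, since the values are counts. Of 1786 alternatives of 79 named miRNA and comparison pairs, 1721 kept direction and side of the threshold, 24 passed it and 41 turned direction. No pair passed in the main test, so keeping the side means staying uncalled, and no call could be lost. The 1721 are thus no measure of support. Of 634 alternatives of 38 list calls, 370 kept direction and call, 238 lost the call and 26 turned in camera's direction or in the sign of the mean. The causes were not tested. A positive estimated correlation widens the null of a list, but its part in the lost calls was not measured. For the striated muscle list at 24W that correlation was -0.125, yet the unadjusted camera p rose from 0.0272 to 0.0546. Depth limits low-count miRNAs most in 24W head replicate 2.

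edgeR's counts of 0 became, for tail against head over both ages, 13 with a replicate block, 1 with total counts, 8 with DESeq2 and 0 to 5 in leave-one-out fits; at 24W 5 with DESeq2; at 6W 1 with the block. For 24W against 6W they became 1 in head with total counts, 1 in tail with DESeq2, and over both regions 2 with total counts, 4 with the acinar covariate and 3 with DESeq2. The total-count calls, all lower at 24W, were miR-142-5p in head (log2 fold change -4.55) and miR-142-5p (-3.96) and miR-142-3p (-3.35) over both regions. Both are members of the leukocyte list. The acinar covariate gave miR-184, miR-130b-3p and miR-92a-3p lower and miR-488-3p higher. The labels do not state whether head and tail libraries of the same number are paired. Their correlation was 0.66, -0.19 and 0.56 at 6W and 0.44, 0.09 and 0.48 at 24W, and 4 of 6 were closest to their own number. The highest correlation with another number was 0.107, 0.149 and 0.071 at 6W and 0.208, 0.137 and -0.303 at 24W. Numbers 1 and 3 thus lean toward a link by number at both ages, and number 2 does not. These values neither show a pairing nor exclude one, so the block's counts stand beside those of the main test. The number of lists called was 0 with an estimated correlation, with fry in one direction and with fry in either direction in all 7 comparisons. At 24W it was 3 without the 3 head libraries and 2 to 8 in leave-one-out fits. It was 2 to 5 in leave-one-out fits for age in head. For age in tail it was 4 with the acinar covariate and 3 to 6 in leave-one-out fits. For the interaction it was 2 and 1 to 6. The agreement of tail-against-head values was 0.37 to 0.73 in leave-one-out fits and 0.034 without the 3 head libraries, and that of age values 0.23 to 0.65 and 0.30.

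For tail against head over both ages, total counts gave 0.12 for miR-217-5p, 0.45 for miR-216b-5p, 0.64 for miR-25-3p, 0.092 for miR-92a-3p, 0.46 for miR-26a-5p, 0.062 for miR-142-5p, 0.39 for miR-146a-5p, 0.076 for miR-192-5p, 0.31 for miR-128-3p, 0.72 for miR-451-5p and 0.56 for miR-126a-3p, from negative values. In that setting 157 of all 378 miRNAs changed sign, and their median moved from -0.031 to 0.79. Each of the values just given lay below that median, so none rose above the bulk of the miRNAs. The acinar covariate gave 0.11 for miR-216b-5p, and leaving out the 3 head libraries gave 0.074 for miR-25-3p, 0.42 for miR-128-3p and 0.046 for miR-451-5p. miR-126a-3p, at -0.01, became 0.054 with the block, 0.0039 with RLE, 0.11 with the strict filter, 0.051 with limma-voom and 0.0039 with DESeq2. Leave-one-out ranges were -1.03 to 0.038 for miR-216b-5p, -0.64 to 0.070 for miR-451-5p and -0.49 to 0.46 for miR-126a-3p. For age over both regions, miR-148a-3p became -0.024 with the acinar covariate (leave-one-out -0.54 to 1.15), miR-34a-5p 0.27 with limma-voom (-1.09 to 0.056), let-7f-5p 0.032 with limma-voom (-0.17 to 0.10), and miR-210-3p -0.26 with total counts; miR-217-5p ranged from -0.0089 to 0.93.

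Mean list values that turned with total counts were, at 24W, 0.54 for leukocyte, 0.34 for mesenchymal, 0.041 for neuronal, 0.36 for gut and liver and 0.87 for miR-17-92. Over both ages they were 0.15 for leukocyte, 0.10 for neuronal, 0.081 for gut and liver and 0.28 for miR-17-92. For age in head they were -0.29 for Dlk1-Dio3 and -0.26 for miR-29, and for the interaction 0.33 for islet and 0.78 for Dlk1-Dio3. The median of all miRNAs with total counts was 1.51 at 24W, 0.79 over both ages, -0.92 for age in head and 1.09 for the interaction. Each turned mean stayed on the same side of the median of all miRNAs as in the main test. Without the 3 head libraries, which leaves 1 library in 24W head and tests no direction there, leukocyte became 0.62 and miR-17-92 0.58 at 24W, and neuronal 0.11 over both ages. With the acinar covariate, which removes the acinar list by construction, acinar became 0.010 at 6W, -0.033 for age in tail and -0.023 for the interaction, where miR-200 became -0.12 and Dlk1-Dio3 0.27. Leave-one-out means of Dlk1-Dio3 ranged from -0.065 to 0.74 for age in tail and from -0.70 to 0.16 for the interaction.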

Other observations

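All tests of explanations in this part were set after the values had been seen. Other gene groups gave these list means. The striated muscle list averaged 3.76 log2 CPM in head and 3.1799 in tail, a difference of -0.58 (exact permutation p = 0.01, adjusted p = 0.17 over 34 comparisons, n = 6 each). The miR-29 family averaged 4.63 at 6W and 5.31 at 24W, a difference of 0.68 (exact permutation p = 0.005, adjusted p = 0.17, n = 6 each). The islet list differed by 0.68 between tail and head (exact permutation p = 0.025, adjusted p = 0.283, n = 6 each), and none of the 3 passed the correction. Over 400 relabelings this exact p cannot go below 0.005, the value of the miR-29 family. A single measure at 0.005 is adjusted to 0.17 over 34 comparisons, so missing the correction does not argue against a difference. The acinar list had an r of 0.58 with miR-148a-3p over the 12 libraries (permutation p = 0.0476, adjusted 0.0572 over 6 relations; rho 0.62, p = 0.0345, adjusted 0.0561), 0.54 without the libraries farthest in acinar level. With the leukocyte list it had an r of 0.18 (permutation p = 0.58, adjusted 0.58; rho 0.18, p = 0.573, adjusted 0.573), -0.35 without those libraries. With the miR-17-92 list it had an r of 0.63 (permutation p = 0.0258, adjusted 0.0387; rho 0.41, p = 0.192, adjusted 0.23), which rests on those libraries (0.12 without them).

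Other splits of the libraries were counted for each comparison. For miRNAs, edgeR's count of 0 (51 at an unadjusted p under 0.05, 8 by DESeq2 and 0 by limma-voom for tail against head over both ages) is reached by every split, 100 of 100 for tail against head over both ages, age over both regions and the interaction. No split can call fewer than 0, so this says nothing about chance. The highest other splits called 90, 35 and 19 miRNAs, which may point to a structure of the samples, but no value without such structure was computed for comparison and none was tested. For lists over both ages, 15 of 100 splits gave at least the 7 of tail against head and 60 of 100 at least the 4 of age, with 9 the highest other in both, so chance cannot be excluded. The 10 splits of 3 against 3 are too few for a share under 0.05. There, 10 of 10 splits reached the count of 0 miRNAs in all 4 comparisons, again because no split can call fewer, with highest others of 0 at 24W, 1 at 6W, 4 for age in head and 1 for age in tail. For lists, 2 splits reached the 7 at 24W, 7 the 4 at 6W, 8 the 3 for age in head and 2 the 7 for age in tail, with 7 the highest other in each. The first principal component of the libraries held 40.1% of the variance and the next 15.6%.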
